A study of Drosophila melanogaster with 2 samples.

How the data were processed

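Trl ChIP-seq was done on chromatin of Drosophila melanogaster embryos of 16 to 24 h, which per the labels' protocols was fixed with formaldehyde and sonicated before immunoprecipitation with a specific antibody, with part of the chromatin kept as input. There were 2 samples, 1 immunoprecipitated sample and 1 input, and 1 file, a peak list of the immunoprecipitated sample. Per the file headers the peaks were called with MACS, and per the submitters' processing notes the reads were aligned with Bowtie and the build was BDGP5. The versions, the settings, the read filters and the number of reads are not given in the sources used here. Per the labels, the sample's title names replicates 1 and 2 together. Whether the reads were pooled before calling or the calls combined afterwards is not given in the sources used here, and replicates could therefore not be compared.

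For each peak the deposited file gives a chromosome, a start, an end and a score. The scale of the score the authors deposited is not stated in the file. It was used within the list only, to rank and filter peaks and to compare median scores between sets of peaks, whose differences carry no known unit. The starts were taken as counted from 0 and printed here counted from 1, and 2 peaks start before the first base of their sequence. No sequence and no gene is given for a peak. The gene table at hand belongs to Release 6, another build, so no gene was assigned to a peak. The tests that need genes or sequence of BDGP5 were not run: peaks at transcription start sites, peaks by genomic feature, scores by feature, motifs in peaks (12 motifs fixed beforehand) and gene lists (20 lists fixed beforehand).

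From the file, widths, covered length and scores were summarised over all 5195 peaks, and the comparisons used the 5188 peaks on the arms 2L, 2R, 3L, 3R, 4 and X. Arm lengths were taken as the span from the first to the last peak of each arm, since no genome of this build was used. This leaves out peak-free ends and so raises densities. The size of this effect was not measured and may differ between arms, including arm 4 with its short span of 1.20 Mb. Densities were compared with placement in proportion to span by 2-sided exact binomial tests, with Benjamini-Hochberg adjustment over 6 arms and a threshold of 0.05. Intervals of densities are exact Poisson intervals and those of shares Wilson intervals, at 95%, and cover counting error only. Spacing was tested against 1000 random placements of the centres with the same number on each arm. Medians were compared by 2-sided permutation tests with 100000 resamples. All p-values treat peaks, bins or placements of this 1 list as units and say nothing about variation between embryos or libraries.

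The comparisons, the alternatives and the rule for named sites were written before the data were examined. The rule named the gene nearest to each of the 20 highest-scoring peaks and, where no annotation of the build was at hand, those 20 peaks by position. The widest peaks, the densest bins and windows, the chains and the longest peak-free stretches were added after seeing the data and taken from the top of each ranking. The alternatives set beforehand that could be run were restriction to peaks scored at or above the median, merging of peaks within 1000 bp, and distances of 5 and 20 kb. Added after seeing the data were placement within 1 Mb bins, placement without overlap (also with the deposited and the random peaks merged alike), and permutation of 1 Mb bins between arms, the last with 100000 resamples.

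The tests were run on simulated lists of 5188 peaks on the same spans. The spacing test called 0 of 20 lists with uniform placement and 20 of 20 lists in which 10% of the peaks were set within 8 kb of another. With arm 2L at 86% of the other arms' density, the binomial test called it in 96 of 100 lists. With arm 4 at 65%, it called it in 49 of 100 lists. With no arm changed, it called 2L in 0 and arm 4 in 1 of 100 lists. The comparison of medians called 16 of 20 lists when the scores of 1 arm were set to 80%, and 0 of 20 when unchanged. The settings of 86% and 65% equal the ratios observed for these arms. The unchanged lists drew peaks independently of each other, so their low rates of calls do not carry over to grouped peaks. The simulated tests of spacing and medians used fewer placements and resamples than the tests of the deposited list. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.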

Results

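The binding sites of the Trl protein were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in Drosophila melanogaster embryos of 16 to 24 h. Trl (Trithorax-like) encodes the GAGA factor, a zinc-finger protein that binds GA-rich DNA and is known from promoters and from Polycomb response elements. The 2 samples were 1 immunoprecipitated sample, whose title names replicates 1 and 2 together, and 1 chromatin input. The immunoprecipitated sample had 1 deposited peak list, and per the series' design text the input was the control. No value per replicate was used here, so no difference below has a replicate check, and the errors given cover counting or random placement only. The read depth behind the peaks is unknown. The list pairs no peak with a gene, so sites are given by position on build BDGP5, with positions counted from 1.

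The first question was how much of the genome the called Trl peaks covered at this stage. The list held 5195 peaks, of which 5188 lay on the arms 2L, 2R, 3L, 3R, 4 and X. The other 7 lay on heterochromatic or unplaced sequences. The peaks covered 7.87 Mb, and those on the 6 main arms covered 6.59% of the 119.4 Mb between the first and the last peak of each arm. Coverage was highest on 2R (7.61%) and lowest on arm 4 (3.18%), the small, largely heterochromatic autosome. The median width was 1238 bp, with quartiles of 976.5 and 1744.5 bp, and widths ranged from 299 to 10387 bp.

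The widest peak measured 10387 bp and lay on 2R, from 7516004 to 7526390. The next widest were 9302 bp on X, from 7584281 to 7593582, and 8304 bp on 2L, from 243127 to 251430. A peak of 8298 bp on 3L, from 14747176 to 14755473, and a peak of 7851 bp on 3R, from 7582866 to 7590716, were the widest of their arms. Arm 4 had no peak wider than 4784 bp. In all, 50 peaks were wider than 5000 bp, and 49 of them carried the same score, 3100. The exception, singled out after its values were seen, was a peak of 6790 bp on 2L, from 8090082 to 8096871, with a score of 78.6.

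The authors' scores, which rank the peaks within the list, ran from 50.04 to 3233.06, with a median of 592.04. A score of exactly 3100 was given to 858 peaks, or 16.5% of the list (95% Wilson interval 15.5 to 17.6%), and 39 peaks scored higher. Width and score rose together across peaks (Spearman's rho = 0.81 over 5195 peaks), and also among the 4298 peaks scored under 3100 (rho = 0.73). Peaks of 1 list are not independent replicates, so no p-value is attached to these coefficients.

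**Figure D1:**
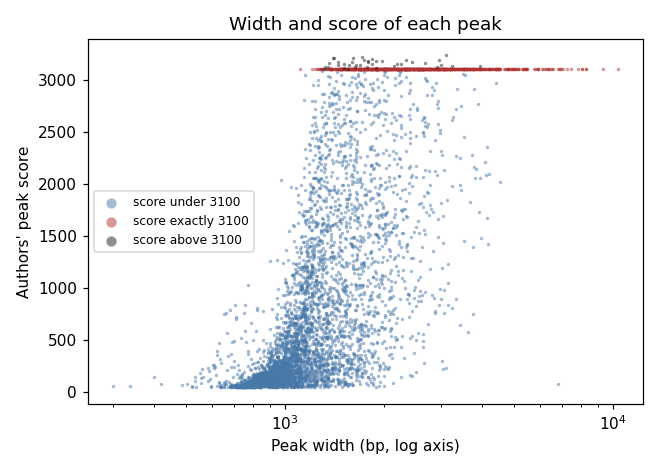
Each point is 1 of the 5195 peaks, with its width in bp on a log axis and the authors' score on a linear axis. The 858 peaks with a score of exactly 3100 form a horizontal line that reaches the widest peak, 10387 bp, while the 39 peaks scored higher sit above the narrower part of that line.

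The 20 peaks with the highest scores lay on 3R and X (6 peaks each), 3L (4 peaks), 2R (3 peaks) and 2L (1 peak), and none lay on arm 4. In proportion to the peaks per arm, 4.79 would be expected on 3R, 3.77 on X and 3.30 on 2L. The highest score, 3233.06, belonged to a peak on 3R from 302353 to 305447. It was followed by peaks on 3L from 6488413 to 6490136 (score 3221.92), on 2R from 14175608 to 14177023 (score 3212.31), on 3L from 21469306 to 21470703 (score 3209.14) and on X from 12489777 to 12491388 (score 3208.83). The highest-scoring peak of 2L lay from 5236657 to 5238444, with a score of 3177.26. Among the 6 peaks on X, 2 lay close together, from 14917377 to 14919115 and from 14937035 to 14938927. These 20 peaks had a median width of 1790.5 bp and ranged from 1359 to 3095 bp, so none was among the widest regions given above. The 858 peaks tied at a score of 3100 had a median width of 2396 bp. As the scale of the score is not stated, the order of these and the higher-scored peaks is that of the listed scores only. The 20 peaks and their spread over the arms follow that listed order and need not be those of the strongest binding.

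The second comparison was between chromosome arms. Peak by peak, Trl was densest on 2R, intermediate on 3L, 3R and X, and least dense on 2L and on arm 4. The density was 47.9 peaks per Mb on 2R (95% exact Poisson interval 45.0 to 51.0), 44.6 on 3R (42.1 to 47.1), 44.2 on 3L (41.6 to 46.9) and 44.0 on X (41.3 to 46.9). It was 37.4 on 2L (34.9 to 40.0) and 28.4 on arm 4 (19.6 to 39.6), against 43.4 over all 6 arms. Counts on X and the 2 arms of chromosome 3 did not differ detectably from placement in proportion to length (ratios of observed to expected of 1.01 for X, 1.02 for 3L and 1.03 for 3R, adjusted p of 0.63, 0.627 and 0.464 in 2-sided exact binomial tests, Benjamini-Hochberg over 6 arms).

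Arm 2L held 855 peaks where 994 were expected, a ratio of 0.86 (adjusted p = 3.88e-06, exact binomial test). Arm 2R held 1010 where 916 were expected, a ratio of 1.10 (adjusted p = 0.00198, exact binomial test). Arm 4 held 34 where 52.1 were expected, a ratio of 0.65 (adjusted p = 0.0196, exact binomial test). The binomial test takes peaks as independent, which the grouping described below does not bear out. When whole 1 Mb bins were permuted between each arm and the others, the 2L bins held 38.2 ± 10.7 peaks (SD, 22 bins) and the bins of the other arms 45.1 ± 12.96 (SD, 95 bins), with an adjusted permutation p of 0.113 for 2L and 0.271 for 2R. Before adjustment, the permutation p of this bin test was 0.0225 for 2L and 0.109 for 2R. After adjustment, neither difference stood out from the spread between regions of 1 Mb. The call on arm 4 was also lost after peaks within 1000 bp were merged (ratio 0.68, adjusted p = 0.0513, exact binomial test).

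**Figure D2:**
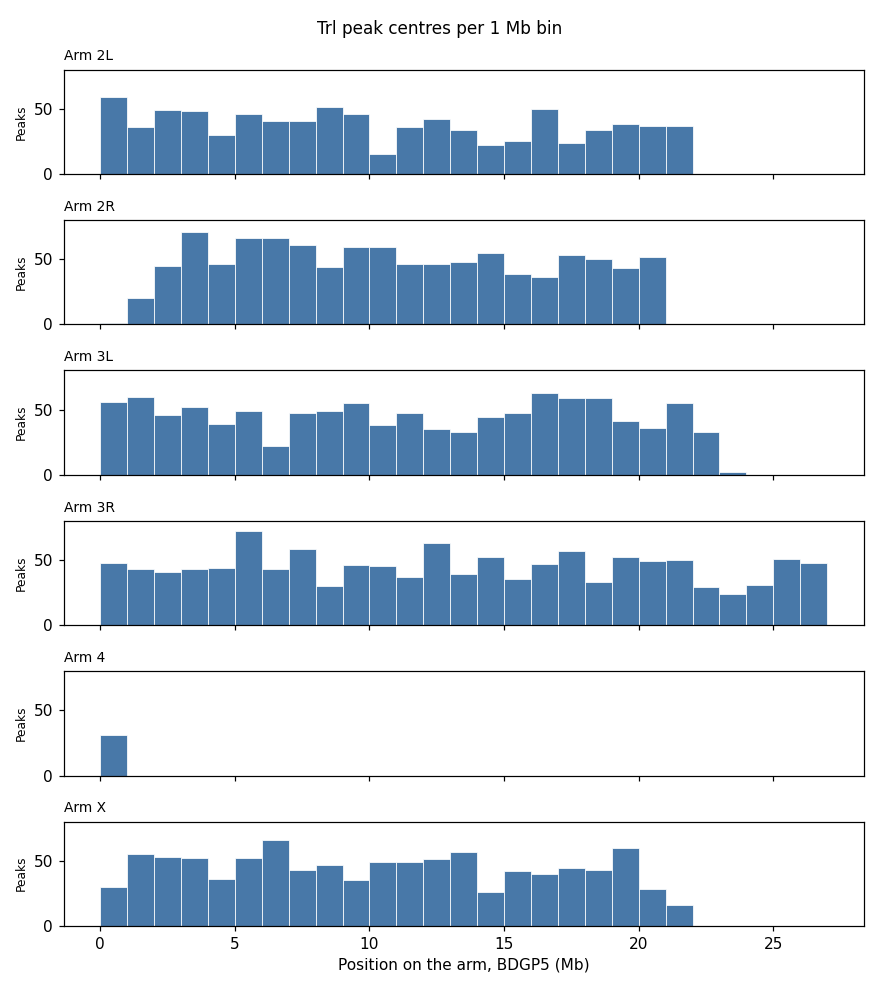
Bars give the number of Trl peak centres in each full 1 Mb bin along the 6 main arms (position in Mb on BDGP5, counts on a linear axis from 0). The first bin of 2R holds 1 peak and the bin of 3L that starts at 23000001 holds 2, while the fullest bin, on 3R from 5000001, holds 72.

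Within arms, the densest 1 Mb bins were on 3R from 5000001 to 6000000 (72 peaks), on 2R from 3000001 to 4000000 (71 peaks), and on 2R from 5000001 to 6000000, on 2R from 6000001 to 7000000 and on X from 6000001 to 7000000 (66 peaks each). The longest stretches without a peak between the first and the last peak of an arm lay on 2R from 74410 to 1012995 (939 kb), on 3L from 23200087 to 24027300 (827 kb), on 2R from 1014574 to 1551491 (537 kb) and on X from 21447252 to 21882308 (435 kb). The longest on 2L ran from 10376917 to 10676573 (299.7 kb), inside the sparsest bin of that arm, which held 15 peaks from 10000001 to 11000000. The longest on arm 4 ran from 579121 to 809094 (229.97 kb).

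A further comparison asked whether Trl peaks lie in groups. Of the 5188 peaks on the main arms, 3505 had another peak centre within 10 kb, which is 67.6% (95% Wilson interval 66.3 to 68.8%). In 1000 random placements of the same number of peaks on each arm, this share was 58.1% ± 0.76 (SD) and at most 60.2% (1-sided permutation test by random placement, p = 0.001, the smallest that these placements can give). The share was above the highest random value on 5 arms: 71.9% on X against 58.5% at random, 71.7% on 2R against 61.6%, 66.7% on 3L against 58.7%, 65.2% on 3R against 59.0% and 62.5% on 2L against 52.7% (adjusted p = 0.0012 each, the same permutation test, Benjamini-Hochberg over 6 arms). On arm 4, 21 of 34 peaks had such a neighbour, 61.8% against 42.1% at random (adjusted p = 0.037, permutation test by random placement).

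The excess was 9.43 percentage points at 10 kb, 9.45 at 5 kb and 3.61 at 20 kb. It narrowed to 4.34 points when peaks within 1000 bp of each other were first merged into 4560 regions, and was still above the highest of the random placements of those regions (57.9% against 56.2%). Those random centres, unlike merged regions, may lie within 1000 bp of each other. With random placements that forbade overlap and were merged in the same way, the excess was 8.18 points, against 12.9 without merging in either. At 2 kb the observed share, 13.1%, was below the random mean of 16.04%. The random centres may lie closer together than peaks with a width can.

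**Figure D3:**
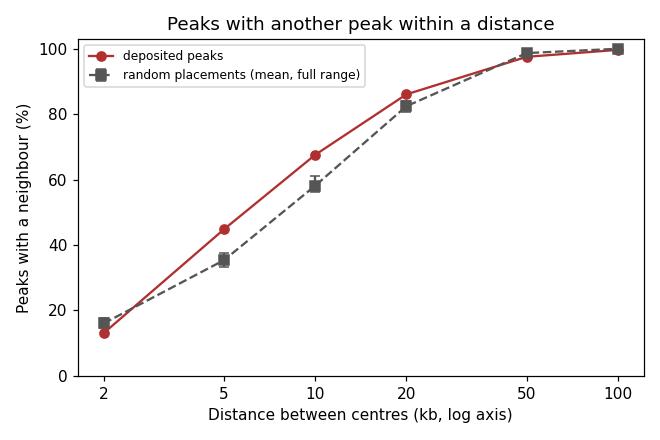
The share of the 5188 peaks on the main arms with another peak centre within a given distance (kb, log axis) is shown in red, and the mean of 200 random placements, with bars for their full range, in grey. The deposited peaks lie above the random range at 5, 10 and 20 kb (44.8, 67.6 and 86.0%) and below it at 2, 50 and 100 kb.

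Chained together wherever the gap between neighbours was at most 10 kb, the peaks formed 2668 chains, of which 1482 were single peaks. There were 17 chains of 10 or more peaks, holding 203 peaks, where 200 random placements that kept the peaks' widths and forbade overlap gave 0 to 3 such chains (1-sided permutation p = 0.005, the smallest they can give). Those placements gave 1928 to 2134 single peaks. Their longest chain held 7 to 16 peaks, with a median of 9, against 15 observed (1-sided permutation p = 0.0249). The longest 3 chains held 15 peaks each: 2R from 7479381 to 7554893, which includes the widest peak of the list, 3L from 7796938 to 7862450, and X from 3565299 to 3618682. Peaks covered 55.5%, 36.8% and 56.8% of these regions. A chain of 14 lay on X from 2161741 to 2250619, a chain of 13 on 2L from 2874091 to 2959631, and chains of 12 on 3R from 12046647 to 12086675, on 3R from 17405570 to 17463638 and on X from 12525672 to 12568857. The first of these on 3R was the most fully covered of the 8, with peaks over 70.8% of its 40.0 kb. The chain of 13 on 2L had 26.04% of its length in peaks. Fixed windows of 100 kb held at most 15 peaks: 2R from 9800001, 3L from 7800001 and from 17900001, and X from 1800001. A maximum this high also occurred in 1000 random placements that, unlike those of the chains, allowed overlap and reached 18 (1-sided permutation p = 0.0659). Random centres may lie closer together than peaks with a width can, so this result cannot be set against that of the chains.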

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

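One signal lay outside the sequences used in the comparisons and is listed for that reason alone, with no control list to compare it with: 7 peaks were called on heterochromatic or unplaced sequences. They were 3 on 3RHet, from 2373995 to 2374765, 2379837 to 2380833 and 2473591 to 2475012, and 1 each on 3LHet (1394968 to 1396178), 2RHet (ending at 441), U (5630679 to 5631209) and Uextra (438914 to 439813). Their scores ran from 151.44 on U to 1286.23 on 3RHet. It was asked whether they could be calls just past the authors' threshold. Their median score of 472.05 lay between the lower quartile (164.8) and the median (592.9) of the main arms, with 1 of the 7 below that lower quartile. The lowest score in the list was 50.04. By the rule set for this question, a median below that quartile would speak for such calls and one above the main arms' median against them. The median lay between the 2, so the question stays undecided for the 7 peaks as a set. The highest score, 1286.23, argues against all 7 being calls just past the threshold, and the lowest-scored of them may be. Reads from repeats shared with other sequences were not tested, since no read or genome was used, and the design offers no biological explanation to set against them.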

How the results depend on the processing

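The alternatives of bin permutation and of the other placements were chosen after seeing the data. With only the peaks scored at or above the median, the list shrank by construction to 2598 peaks with a median width of 1682 bp and 5.14 Mb covered. The calls on 2L and 2R held in those peaks and after merging within 1000 bp, but not when whole 1 Mb bins were permuted between arms (ratios of 0.85 and 1.12 to the other arms, adjusted permutation p = 0.113 and 0.271), a test with bins instead of peaks as units. Arm 4 kept its call among the higher-scoring peaks (ratio 0.50) and lost it after merging (ratio 0.68, adjusted p = 0.0513), where fewer regions are counted, and with 1 full bin it could not enter the bin permutation. The ratio of X, never past the threshold, was 1.01 with all peaks, 0.95 among the higher-scoring peaks and 0.98 after merging. The excess of neighbours, tested at 10 kb, kept its direction and its call at 5 and 20 kb, among the higher-scoring peaks, after merging and with the 3 other placements, from 3.61 percentage points at 20 kb to 12.9 with placements that forbid overlap. At 2, 50 and 100 kb the observed shares (13.1, 97.5 and 99.6%) lay below the random range instead. The span as the arm length was the value reported, so that alternative adds nothing, and the alternatives of the tests that need genes or sequence were not run. No paired analysis was possible because there was only 1 immunoprecipitated sample and 1 input, and the input had no values here. No replicate could be left out of 1 list. What depth limits is unknown, since no read numbers were used.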

Other observations

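The arms' ends next to the centromere differed in Trl peaks. In the first 2 Mb of 2R there were 10.5 peaks per Mb (95% exact Poisson interval 6.50 to 16.1) against 51.7 on the rest of the arm. In the last 2 Mb before the final peak there were 16.5 on 3L (11.4 to 23.2) against 46.7, 18.5 on X (13.03 to 25.5) against 46.6, and 29.0 on 2L (22.02 to 37.5) against 38.2. The first 2 Mb of 3R held 45.5 peaks per Mb (36.6 to 55.9), close to the 44.5 on its rest. These regions were chosen after seeing the data and the cause was not tested.

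The comparisons of scores and widths below were not part of the design fixed before the data were examined and were added after seeing the list, as were their alternatives and the other placements of peaks. The merging of peaks in the test of spacing was fixed beforehand. The permutation tests of medians formed a family of 5, and adjusted values are Benjamini-Hochberg over these.

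The 858 peaks tied at a score of 3100 had a median width of 2396 bp, 619 bp more than the 1777 bp of the 39 peaks scored higher (permutation p = 0.00323, adjusted p = 0.00807). The peaks scored higher were not detectably different in width from the 42 peaks within the same distance under the tied score (median 1989 bp, permutation p = 0.162, adjusted p = 0.162). This is consistent with a floor on very small p-values, under which the tied score may stand for peaks at least as strong as those scored higher. If so, the 20 highest-scoring peaks need not be the strongest of the list, and the 858 tied peaks cannot be ranked by score. The scale of the score is not stated, so differences of median scores below show direction and not a size of binding, and width is only an indirect measure of strength.

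For the grouping of peaks, the tables argue against 2 technical explanations as the whole cause. If broad regions split by peak calling at gaps up to 1000 bp were the cause, merging across such gaps should have ended the excess. Instead, 57.9% of the merged regions still had a neighbour within 10 kb, above the highest of the random placements (56.2%). Those random centres could lie closer than merged regions can. With placements that forbade overlap and were merged alike, the excess was 8.18 points, against 12.9 unmerged. What share of it splitting accounts for stays open. Splitting at gaps wider than 1000 bp would not be undone by this merging and was not tested. If density varying over 1 Mb were the cause, placement within each peak's own 1 Mb bin should have matched the observed share, which was instead 7.78 points above the mean of those placements and above their maximum of 61.8%. Variation in genes, repeats or mappability below 1 Mb stays open, and no biological explanation was tested.

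On the X, peaks were narrower than on 2L, 2R, 3L and 3R, with a median width of 1141 bp over 977 peaks against 1267 bp over 4177 (permutation p = 1e-05, the smallest that the resamples can give, adjusted p = 5e-05). This test took peaks as independent, and no alternative by 1 Mb bins or after merging was run for width. The median score of the peaks on the X was 508.36 against 617.84. One hypothesis was that embryos of both sexes hold fewer copies of the X than of autosomes, which could lower its scores. The difference of -109.48 had a permutation p of 0.04 and an adjusted p of 0.05 that missed the threshold before rounding, so the hypothesis stays open. The difference was -125.2 among the peaks scored at or above the median (permutation p = 0.33), -69.8 without peaks scored 3100 or more (permutation p = 0.0271) and -184.4 between medians of 1 Mb bins (permutation p = 0.0076). Arm 4, an autosome outside this comparison, had a lower median score still, 301.13 over 34 peaks, so a low score is not confined to the X. Its score was not tested and does not decide the hypothesis. On 2L, 2R, 3L and 3R the median scores ran from 598.36 to 646.83, each above that of the X.

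A second hypothesis, that grouped peaks are stronger than isolated ones, stays undecided. The 3505 peaks with a neighbour within 10 kb had a median score 100.9 above that of the other 1683 (627.18 against 526.28, permutation p = 0.0232, adjusted p = 0.0386). The difference did not pass the test after merging peaks within 1000 bp (103.7, permutation p = 0.0788), at 5 kb (37.8, permutation p = 0.362) or at 20 kb (41.4, permutation p = 0.49).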
